A study of Mus musculus with 6 samples.

How the data were processed

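Total RNA of 3 ESC and 3 NPC samples of the 46c line was extracted with a Roche kit, amplified in a single round, labelled with Cy3 and hybridised to single-colour Agilent arrays, per the labels' protocols. The design text calls the samples of a group biological replicates. The deposited table holds log2 values for 55681 probes on 6 arrays, with no missing value. The base of the logarithm is not given in the sources used here and was taken as 2 from the range of 1.03 to 16.18. The sorted values of the 6 columns were identical (largest difference 0), so the authors' values had been quantile normalised across arrays. The tool limma is named in the submitters' processing notes, with no version. Background correction, detection calls and filters are not given in the sources used here, so it is unknown which probes were above background. Slide and scan batches were not analysed here. Quantile normalisation forces equal distributions on all arrays, so a change that moved most transcripts 1 way would not be visible. Amplification and log-scale signals near background can distort fold changes of dim probes.

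Probes were named through the platform annotation: 30626 probes had 1 gene symbol, 0 had several and 25055 are unnamed here. The Entrez IDs of 30332 named probes were in the RefSeq gene table of assembly GRCm38.p6, which was used for names only. No coordinates are printed, since the build behind the probes is not given in the sources used here. Of 6807 genes with more than 1 probe, the probe with the highest mean over all 6 arrays was used; 9 genes had probes called in opposite directions. No probe was left out for low signal and no further normalisation was applied.

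NPC were compared with ESC by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) on 21893 genes, without covariates, with a Benjamini-Hochberg adjusted p under 0.05. A 2-fold count required an absolute log2 fold change of at least 1 as well. Lists were tested with camera at its preset inter-gene correlation of 0.01, two-sided, and adjusted over 39 lists. The test, the alternatives listed at the outset, the lists and the rule for naming genes were chosen before the data were examined. The lists hold 766 genes, of which 725 were on the array (11 through an older symbol) and 41 were not analysed here. They cover pluripotency factors, the LIF and STAT3 pathway, primed epiblast, neural progenitors, neuronal differentiation, forebrain, midbrain and hindbrain, Hox, mesoderm, endoderm, trophectoderm, neural crest and surface ectoderm, glial, fibroblast, germline and 2-cell stage genes. Chromatin lists cover the H4K16 machinery, HDAC and NuRD, Polycomb, BAF, DNA methylation, and linker histones and heterochromatin. The rest are retinoic acid, Notch, Wnt, FGF and ERK, BMP and Hedgehog genes, G1 regulators, mitotic, epithelial, mesenchymal, cholesterol, glycolysis, amino acid stress, immediate early, p53, imprinted and housekeeping genes. Some genes, such as Klf4, Foxd3 and Myc, stand in more than 1 list, so the shifts of such lists are not independent. With an estimated correlation in camera, only the pluripotency list of the 16 called lists kept an adjusted p under 0.05, and with the replicate block as well it did not (0.372).

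Genes named are Sox1, Pou5f1, Nanog, Kat8 and Sirt1; the 12 largest rises and 12 largest falls among called genes whose groups do not overlap; the 3 members of each list with the largest change past the threshold and the largest called change against the majority; the 2 brightest members where none passed; and any member of the pluripotency, neural progenitor and H4K16 lists.

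The replicate numbers in the sample titles were checked for pairing. The deviations of same-numbered arrays from their group means correlated across genes with r = 0.269, 0.725 and 0.784 for replicates 1, 2 and 3, all over 0.1, so the numbers were taken to pair the samples. NPC replicate 1 correlated more with ESC replicate 2 (r = 0.433) than with ESC replicate 1. The replicate number took up 82.9% of the sum of squares within groups. With 3 arrays per group it would take up a large part without any pairing too. The deviations of a group sum to 0, so the correlations of the replicates are not independent. The test with the replicate number as a block was run as the alternative. All 4512 genes called without the block were compared with the 7807 called with it: 4497 were called by both, 15 only without the block and 3310 only with it, and 0 were called with opposite sign.

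The limma test was run on simulated data for 21893 genes with the means, replicate effects and spread of the real genes, of which 200 were changed. Without the block, 0 of 67 genes changed by 1 on the log2 scale were recovered, 13.4% of 67 changed by 2 and 84.8% of 66 changed by 4, and 0% of the unchanged genes were called. With the block, the shares were 5.97%, 85.1% and 100%, and 0.0323% of the unchanged genes were called. In this simulation the test without the block missed most changes of 1 or 2 on the log2 scale. In the data 20.6% of the genes were called, so the adjusted threshold was easier to pass there than with 200 changed genes. The simulated shares therefore do not give the power of the real test. A gene that did not pass is still not shown to be unchanged. In a second simulation, camera called both of 2 shifted lists and 0 of the others. Apart from replicate effects, which both groups shared, the noise was drawn independently for each gene there. It thus does not show whether the preset correlation of 0.01 holds for the data, where estimates ran from -0.0743 to 0.497 among the lists. Alternatives were other scalings, filters on dim probes, the mean of all probes, every probe counted, other variance models, array weights, a stricter threshold, the replicate block, leaving out each array and an estimated correlation. Figures were drawn with matplotlib 3.10.9.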

Results

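Transcript levels were measured in mouse embryonic stem cells of the 46c line, which carries a GFP reporter at the neural gene Sox1, and in cells made from them by neural differentiation. Undifferentiated cells (ESC) were set against cells sorted on GFP after 5 days of differentiation with neural medium supplements (NPC), with 3 arrays per group from biological replicates. The labels do not say which GFP gate was kept. Each value is a quantile-normalised log2 signal of a single-colour Agilent array with 55681 probes, of which 30626 carried 1 gene symbol and stood for 21893 genes. All arrays had a median of 5.32 and ran from 1.03 to 16.18, and the number of arrays limits the precision. Unless stated otherwise, changes are log2 fold changes of NPC against ESC ± SE with n = 3 arrays per group, and p-values are limma's, adjusted by the Benjamini-Hochberg method. The series title is about acetylation of histone H4 at lysine 16 (H4K16) in active genes and enhancers of ES cells, and the arrays give the expression side of the change from ES cell to neural progenitor.

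Of the pluripotency genes, 26 of 31 fell, and of the neural progenitor genes, 32 of 44 rose. Pou5f1, which encodes the core pluripotency factor Oct4, fell by 7.75 ± 0.32, and Zfp42, a marker of naive ES cells, fell by 8.56 ± 0.37. Fabp7, a lipid-binding protein of radial glia, rose by 10.54 ± 0.24, and Dbx1, a homeodomain factor of the ventricular zone, rose by 10.40 ± 0.17. With values under 6 set to 6 these rises were 8.17 and 7.28. Cdh1 was among 17 of 22 epithelial junction genes that fell, while Cdh2 and Hoxb2 rose. Of the 21893 genes tested, 2423 were higher and 2089 lower in NPC, together 20.6%, and 4138 differed by at least 2-fold. With the replicate number as a block the counts were 4147 higher and 3660 lower. Without ESC replicate 1 the counts were 1475 and 1289, and without NPC replicate 1 they were 1555 and 1421. With values under 6 set to 6, 1527 were higher and 1297 lower, and 2313 differed by at least 2-fold.

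**Figure D1:**
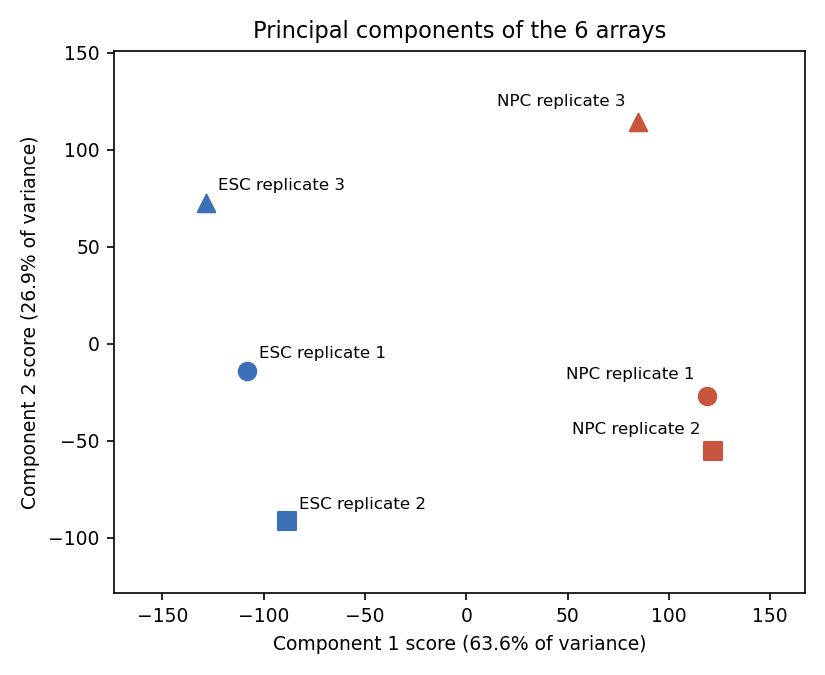
Scores of the 6 arrays on the first 2 principal components of the values of 21893 genes, with colour for the group and marker shape for the replicate number. Component 1 (63.6% of the variance) parted ESC from NPC, and on component 2 (26.9%) both replicate 3 arrays lay above and both replicate 2 arrays below the rest of their group.

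The largest rises included transcription factor genes. Foxb1 rose by 9.86 ± 0.36, Irx3 by 9.78 ± 0.53, Nhlh2 by 9.01 ± 0.26 and Nr2f1, an orphan nuclear receptor of the developing nervous system, by 8.95 ± 0.25. The long noncoding RNA Pantr1, a neighbour of the neural factor gene Pou3f3, rose by 10.33 ± 0.33. Vit, which encodes an extracellular matrix protein, rose by 9.50 ± 0.20. Igfbp5, an IGF-binding protein, rose by 9.43 ± 0.29. The largest falls included Mymx, which encodes a small membrane protein of myoblast fusion, with a change of -9.88 ± 0.56, and Morc1, a germline ATPase, with -9.57 ± 0.66. Tcl1 fell by 8.52 ± 0.39, Wt1 fell by 8.47 ± 0.49, Ano9 fell by 8.46 ± 0.48, Rpl39l fell by 8.33 ± 0.19 and Fgf4, a growth factor of the inner cell mass, fell by 8.34 ± 0.22. Pou5f1-rs4 fell by 8.02 ± 0.37, but it is a near copy of Pou5f1 and its probe may read both, so this value is uncertain. With values under 6 set to 6, Vit differed by 4.65, Foxb1 by 5.49, Nhlh2 by 4.51 and Wt1 by -3.76. With this floor Pantr1 differed by 7.37, Hoxb2 by 7.46, Igfbp5 by 7.20 and Tcl1 by -6.31. The exact folds of these genes and the ranks among the largest changes thus rest on signals near the bottom of the scale, while the change of Pou5f1 stayed at -7.75. Of 175 named genes past the threshold, 65 had a log2 change smaller by 1 or more with this floor, and 44 had one over 1.5 times smaller. The 65 also include Irx3, Ano9, Bcl3, Fgf4, Dppa2, Tfcp2l1, Grhl2, Foxa2, Cyp26b1, Sp5, Spry4 and Epcam. Among the 44 are Hoxb3, Hoxa2, Mymx, Morc1, Rpl39l, Foxd3, Prdm14, Sox9, Pou3f2, Ebf3, Dcx, Egr2, Cdh11, Smarca2, Cbx8, Cdx1, Eomes, Cxcr4, Tfap2b, Tdrkh, Zscan4f and Lgr5. Another probe of the gene did not pass for 34 of the 175, among them Esrrb (-0.03), Phc1 (-0.31), Cdh11 (0.58) and Grhl2 (-0.97), whose other probes were dimmer. With the mean of all probes 20 of the 175 had a change over 1.5 times smaller. These include the 4 just named, Sox1, Otx2, Slc1a2, Gas1, Lgr5, Smarcd2, Dcx (2.89), Zeb2 (3.19), Peg12 (3.25) and Bmp4 (-3.97).

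Of the pluripotency factors and markers, 26 of 31 measured members fell and 0 rose (28 and 0 adjusted over the list alone, 28 and 0 with the block). The median change of the list was -6.38 (camera adjusted p = 2.33e-22, and adjusted p = 0.0473 with an estimated correlation, but 0.372 with the replicate block and an estimated correlation together). Pou5f1 went from 14.42 ± 0.52 in ESC to 6.67 ± 0.27 in NPC (mean ± SD, n = 3 per group, adjusted p = 0.000107). The naive-state factors Klf2, Klf5, Esrrb and Tfcp2l1 fell by 7.28 ± 0.32, 6.60 ± 0.33, 6.16 ± 0.40 and 6.89 ± 0.55. The chromatin-associated Dppa2 and Utf1 fell by 8.28 ± 0.31 and 6.38 ± 0.31, and Prdm14 fell by 7.47 ± 0.46. Nanog did not pass the test: its single probe read 6.93 ± 0.43 in ESC and 7.52 ± 0.32 in NPC, a difference of 0.59 ± 0.30 (adjusted p = 0.258). Whether this dim probe measures Nanog was not checked here. Lin28a, an RNA-binding protein, read 13.52 ± 0.21 and 13.11 ± 0.16 and did not pass (adjusted p = 0.239). Sall4 differed by -1.46 ± 0.46 without passing (adjusted p = 0.0803, 0.0339 with the replicate block), and Trim28, with -0.70 ± 0.28, passed only with the block too (adjusted p = 0.157 and 0.0286). Tdgf1, a coreceptor of Nodal, gave unlike values by probe: its probe of highest mean gave -1.31 and did not pass, whereas its other probes gave -9.77 and -7.68.

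**Figure D2:**
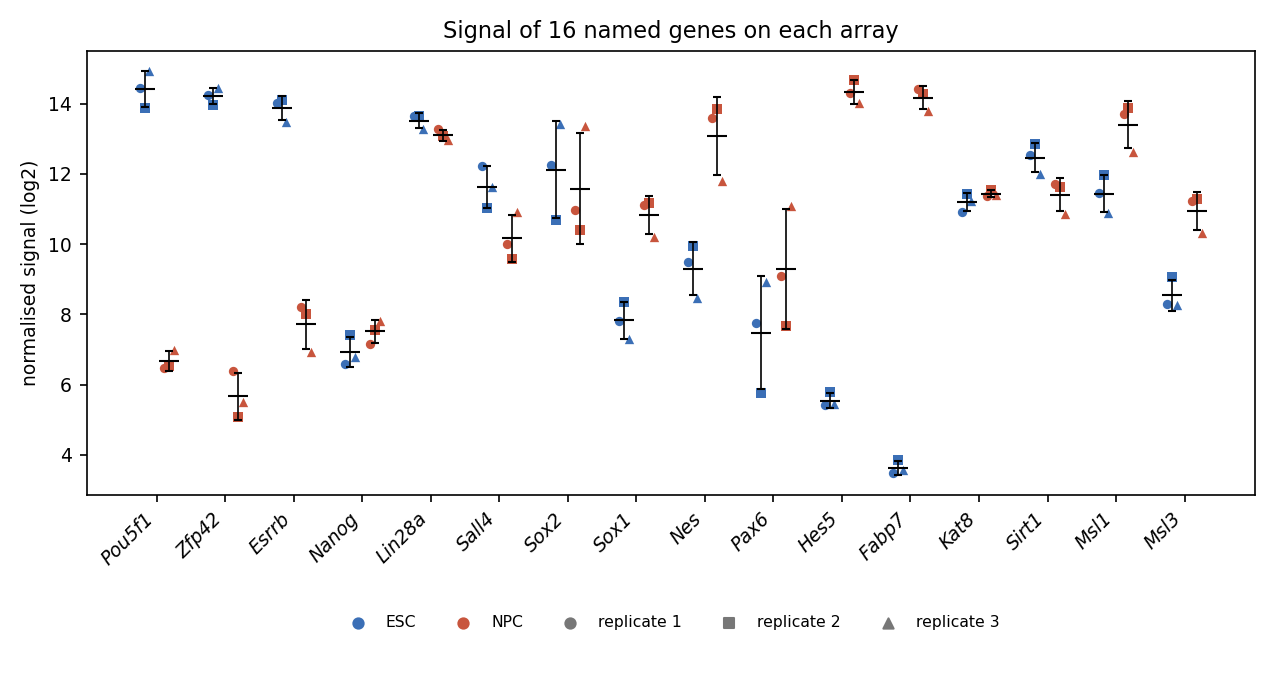
Normalised log2 signal of 16 named genes on each array, with colour for the group, marker shape for the replicate number, and black bars for the group mean ± SD (n = 3). Pou5f1 read between 13.89 and 14.92 on the ESC arrays and between 6.48 and 6.98 on the NPC arrays, whereas the Sox2 and Pax6 values of each group spread widely by replicate number.

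The LIF and STAT3 pathway, which maintains mouse ES cells in culture, was lower in NPC: 7 of 13 measured members fell and 0 rose (8 and 0 adjusted over the list alone, 11 and 0 with the block). Bcl3 fell by 8.37 ± 0.72 and Klf4 fell by 4.75 ± 0.68, and the median was -2.33 (camera adjusted p = 2.5e-05, and 0.0662 as the adjusted p with an estimated correlation). Klf4 and Tfcp2l1 are in the pluripotency list too, so the shifts of both lists are not separate evidence. Of the targets of FGF and ERK signalling, 7 of 13 measured members fell and 0 rose (9 and 0 adjusted over the list alone, 10 and 0 with the block). The feedback inhibitor Spry4 fell by 5.41 ± 0.78, and the ETS factors Etv5 and Etv4 fell by 3.73 ± 0.37 and 3.60 ± 0.52 (camera adjusted p = 0.000227, and adjusted p = 0.186 with an estimated correlation). Markers of the primed epiblast went both ways, as 8 of 17 measured members fell and 5 rose (8 and 7 adjusted over the list alone, 8 and 7 with the block). Foxd3 fell by 7.59 ± 0.54 and Grhl2 fell by 6.23 ± 0.48, while Sox3, which is also a neural progenitor gene, rose by 4.73 ± 0.48; the list as a whole did not pass (camera adjusted p = 0.513).

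Of the neural progenitor factors and markers, 32 of 44 measured members rose and 1 fell (35 and 1 adjusted over the list alone, 36 and 2 with the block). The median change was 3.45 (camera adjusted p = 1.76e-17, and adjusted p = 0.0662 with an estimated correlation). Sox1, whose reporter was used for the sort and which is therefore no finding between the groups, went from 7.83 ± 0.53 to 10.83 ± 0.54, a rise of 3.01 ± 0.39 (adjusted p = 0.00381). Its other probe gave 0.91 and did not pass. Hes5, an effector of Notch signalling, rose by 8.79 ± 0.24, Sox9 by 8.58 ± 0.21, Pou3f2 by 8.57 ± 0.24 and Sox11 by 4.48 ± 0.19. Pax3 and Nkx6-1, patterning genes of the dorsal and the ventral neural tube, rose by 6.28 ± 0.40 and 6.65 ± 0.56. The intermediate filament gene Nes rose by 3.78 ± 0.66 (adjusted p = 0.0108, which became 0.0534 without NPC replicate 1). Sox2, shared by ES cells and neural progenitors, read 12.12 ± 1.39 in ESC and 11.58 ± 1.58 in NPC and did not pass (adjusted p = 0.793). Pax6 differed by 1.81 ± 1.13 with a wide spread between replicates in both groups (adjusted p = 0.357, and 0.00606 with the replicate block). Sox21 differed by 2.81 ± 0.95 (adjusted p = 0.0989, and 0.00418 with the block). Zic5 was the 1 member that fell, by 2.13 ± 0.32. Probes disagreed for Zic1 (-0.81 and 4.52), Msi1 (-0.48 and 3.99) and Rfx4 (2.44 and 5.93), where only the second probe passed. With the replicate block, the first probe of Zic1 passed as a fall (adjusted p = 0.0499), opposite in sign to its other probe.

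Of the genes of neuronal differentiation, 23 of 36 measured members rose and 0 fell (25 and 1 adjusted over the list alone, 26 and 0 with the block). Nhlh2 is given above; Ebf3 rose by 8.85 ± 0.30 and Dcx, a microtubule protein of young neurons, by 6.24 ± 0.94, with 1.61 and 0.84 and no call at its 2 other probes (camera adjusted p = 1.13e-10, and adjusted p = 0.145 with an estimated correlation). In the Notch pathway 10 of 21 measured members rose and 1 fell (14 and 2 adjusted over the list alone, 14 and 1 with the block). Nrarp and Dtx4 rose by 5.36 ± 0.61 and 4.81 ± 0.44, and Rbpj, the DNA-binding partner of Notch, fell by 1.22 ± 0.31 with a call that ended in 5 of 6 leave-one-out fits (highest adjusted p 0.144 without ESC replicate 1), with the mean of all probes and with values under 6 set to 6. The change of Rbpj stayed at -1.22 with the floor of 6 and passed with the replicate block (adjusted p = 0.00556). The list gave a camera adjusted p of 1.69e-05, and an adjusted p of 0.186 with an estimated correlation. In the Hedgehog pathway 5 of 10 measured members rose and 0 fell (7 and 0 adjusted over the list alone, 6 and 0 with the block). The coreceptor genes Gas1 and Boc rose by 4.40 ± 0.67 and 4.12 ± 0.33, although the 2 other probes of Gas1 gave 0.51 and -0.06 and did not pass. Shh itself rose by 4.76 ± 0.92, a call that ended in 3 of 6 leave-one-out fits (highest adjusted p 0.0613 without ESC replicate 1) and with values under 6 set to 6 (adjusted p = 0.774). The camera adjusted p was 0.00648, and the adjusted p was 0.145 with an estimated correlation.

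Of the Hox genes, 11 of 38 measured members rose and 4 fell (11 and 4 adjusted over the list alone, 12 and 4 with the block), with a median of 0.38 (camera adjusted p = 0.00502, and adjusted p = 0.536 with an estimated correlation). Hoxb2 rose by 9.99 ± 0.19, Hoxb3 by 8.90 ± 0.29 and Hoxa2 by 8.88 ± 0.30. In a grouping chosen after the values were seen, 8 of 11 genes of paralog groups 1 to 4 rose and 0 fell. Of groups 5 to 8, 3 of 11 rose and 0 fell. Hoxb8, chosen after its values were seen, rose by 8.11 ± 0.38 (adjusted p = 0.000132). Of groups 9 to 13, 0 of 16 rose and 4 fell. Those 4, Hoxb9, Hoxb13, Hoxc13 and Hoxd13, were named after their values were seen, except Hoxd13, and had ESC means of 3.97 to 5.40. With values under 6 set to 6, none of them fell, 5 genes of groups 1 to 4 rose, and 1 gene of groups 5 to 8 did, Hoxb8, by 3.53. Hoxd13 had a change of -2.80 ± 0.62, and its call ended in 4 of 6 leave-one-out fits (highest adjusted p 0.0995 without ESC replicate 1) and with values under 6 set to 6. Of the midbrain and hindbrain factors, 4 of 18 measured members rose and 1 fell (6 and 1 adjusted over the list alone, 7 and 2 with the block), and the list did not pass (camera adjusted p = 0.0585, and 0.0336 without ESC replicate 2). Irx1 and Irx2 rose by 5.43 ± 0.38 and 4.94 ± 0.22 (the call of Irx2 ended with the mean of all probes), Egr2, a factor of hindbrain rhombomeres, by 4.55 ± 0.31, and Gbx2 fell by 2.47 ± 0.32. Of the forebrain factors, 2 of 16 measured members rose and 2 fell (2 and 2 adjusted over the list alone, 2 and 2 with the block) (camera adjusted p = 0.857). Otx2, which marks epiblast and anterior neural tissue, fell by 4.01 ± 0.41 by the probe used here and gave -0.45 without a call by the other, and Lhx2 rose by 2.79 ± 0.18.

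**Figure D3:**
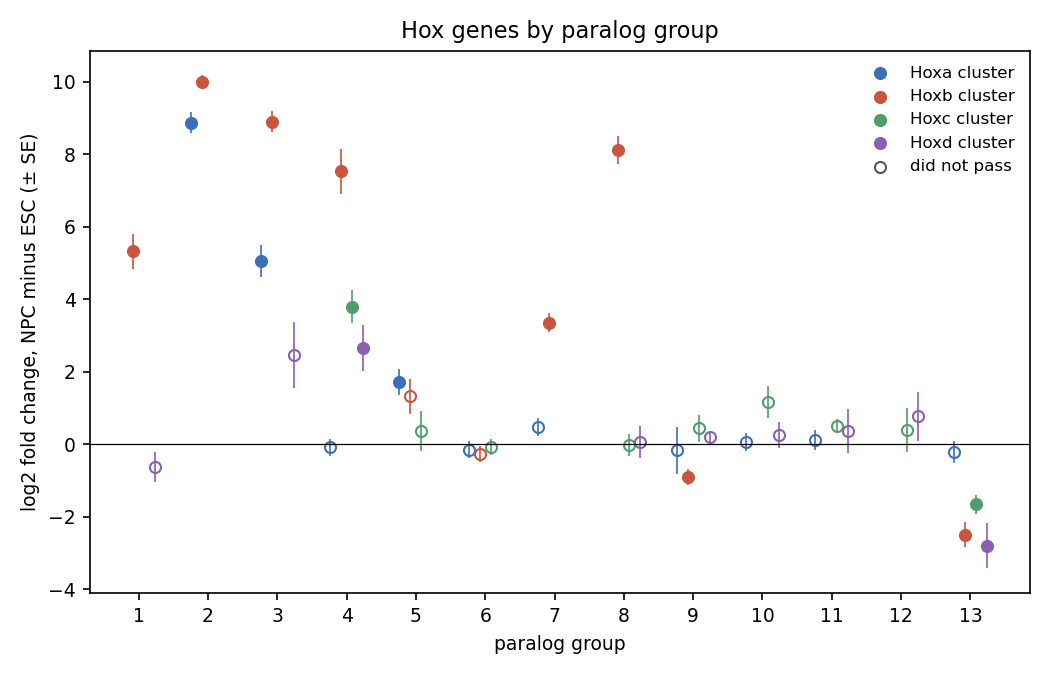
Log2 fold change (NPC minus ESC, ± SE) of 38 Hox genes against their paralog group, with colour for the cluster and filled points for genes past the threshold. The 8 genes that rose in groups 1 to 4 lay between 2.65 and 9.99, Hoxb8 of group 8 stood at 8.11, and in groups 9 to 13 no gene rose.

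Of the epithelial junction genes, 17 of 22 measured members fell and 0 rose (18 and 0 adjusted over the list alone, 18 and 0 with the block). Epcam fell by 6.78 ± 0.72, Cdh1, which encodes E-cadherin, fell by 6.19 ± 0.21 and Cldn6 fell by 5.91 ± 0.43 (median -3.25, camera adjusted p = 2e-13, and adjusted p = 0.0662 with an estimated correlation). Of the mesenchymal and cadherin switch genes, 8 of 14 measured members rose and 0 fell (9 and 2 adjusted over the list alone, 9 and 2 with the block). Cdh2, which encodes N-cadherin, rose by 4.12 ± 0.36, Cdh11 by 7.49 ± 0.55 and Zeb2, a repressor of Cdh1, by 5.84 ± 0.33 (camera adjusted p = 0.000778, and adjusted p = 0.287 with an estimated correlation).

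Transcripts of the H4K16 acetylation machinery as a list did not shift past the threshold (median 0.23, camera adjusted p = 0.437), although 3 of 16 measured members rose and 0 fell (3 and 0 adjusted over the list alone, 4 and 2 with the block). Kat8, the acetyltransferase of H4K16, read 11.20 ± 0.26 in ESC and 11.44 ± 0.10 in NPC (adjusted p = 0.502). Msl3 rose by 2.41 ± 0.37 and Sirt2, a deacetylase, by 1.07 ± 0.18. Msl1, a scaffold of the MSL complex, rose by 1.96 ± 0.44, a call that ended in 4 of 6 leave-one-out fits (highest adjusted p 0.102 without NPC replicate 1) and with values under 6 set to 6 (adjusted p = 0.0788). All values of Msl1 lay above 6, and its change stayed at 1.96 with that floor. With the replicate block Msl1 passed (adjusted p = 0.00264). Its other probes gave 1.26 and 0.78 and did not pass, whereas the mean of all probes did (1.33, adjusted p = 0.00293). Sirt1, a deacetylase that acts on H4K16, read 12.46 ± 0.42 and 11.41 ± 0.47, a difference of -1.06 ± 0.34 that passed only with the replicate block (adjusted p = 0.0851, and 0.0107 with the block). Kat7, at -0.73 ± 0.43, and Kansl3, at 1.09 ± 0.42, likewise passed only with the block (adjusted p = 0.0355 and 0.0102).

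Other chromatin lists held members that moved in both directions. Of the BAF subunits, 7 of 28 measured members rose and 1 fell (8 and 1 adjusted over the list alone, 11 and 1 with the block), with Smarca2 at 4.20 ± 0.25 and Smarce1 at 2.28 ± 0.27 (camera adjusted p = 0.0349). The call of the BAF list was lost with an estimated correlation (adjusted p = 0.284) and with the replicate block (adjusted p = 0.0721), and without NPC replicate 3 the adjusted p was 0.0898. Smarcd2 fell by 1.19 ± 0.21, a call that ended in 1 of 6 leave-one-out fits (adjusted p = 0.0577 without ESC replicate 1) and with the mean of all probes (-0.74, adjusted p = 0.366). Its other, dimmer probe gave -0.30 and did not pass. Of the Polycomb subunits, 6 of 27 measured members rose and 6 fell (7 and 7 adjusted over the list alone, 9 and 11 with the block): Cbx8 and Bmi1 rose by 4.77 ± 0.55 and 3.57 ± 0.36, and Phc1 fell by 2.62 ± 0.33 (camera adjusted p = 0.857). Of the HDAC and NuRD subunits, 4 of 23 measured members rose and 2 fell (4 and 2 adjusted over the list alone, 8 and 3 with the block). Chd3 rose by 3.49 ± 0.44 and Mta3 fell by 2.75 ± 0.26, a call that ended with the mean of all probes (camera adjusted p = 0.601). Of the DNA methylation machinery, 5 of 14 measured members fell and 1 rose (5 and 2 adjusted over the list alone, 6 and 4 with the block); Dnmt3l, a cofactor of the de novo methyltransferases, fell by 7.56 ± 0.34 and Tet1 fell by 3.40 ± 0.46 (camera adjusted p = 0.181). Uhrf2 rose by 1.45 ± 0.34, a call that ended in 5 of 6 leave-one-out fits (highest adjusted p 0.110 without NPC replicate 1), with values under 6 set to 6 and with the mean of all probes (1.06, adjusted p = 0.0998). The change of Uhrf2 stayed at 1.45 with the floor of 6 and passed with the replicate block (adjusted p = 0.0031). Of the linker histones and heterochromatin proteins, 4 of 28 measured members rose and 2 fell (4 and 2 adjusted over the list alone, 8 and 3 with the block); Hmga2 rose by 3.86 ± 0.24 and Lmna fell by 2.23 ± 0.23 (camera adjusted p = 0.277).

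**Figure D4:**
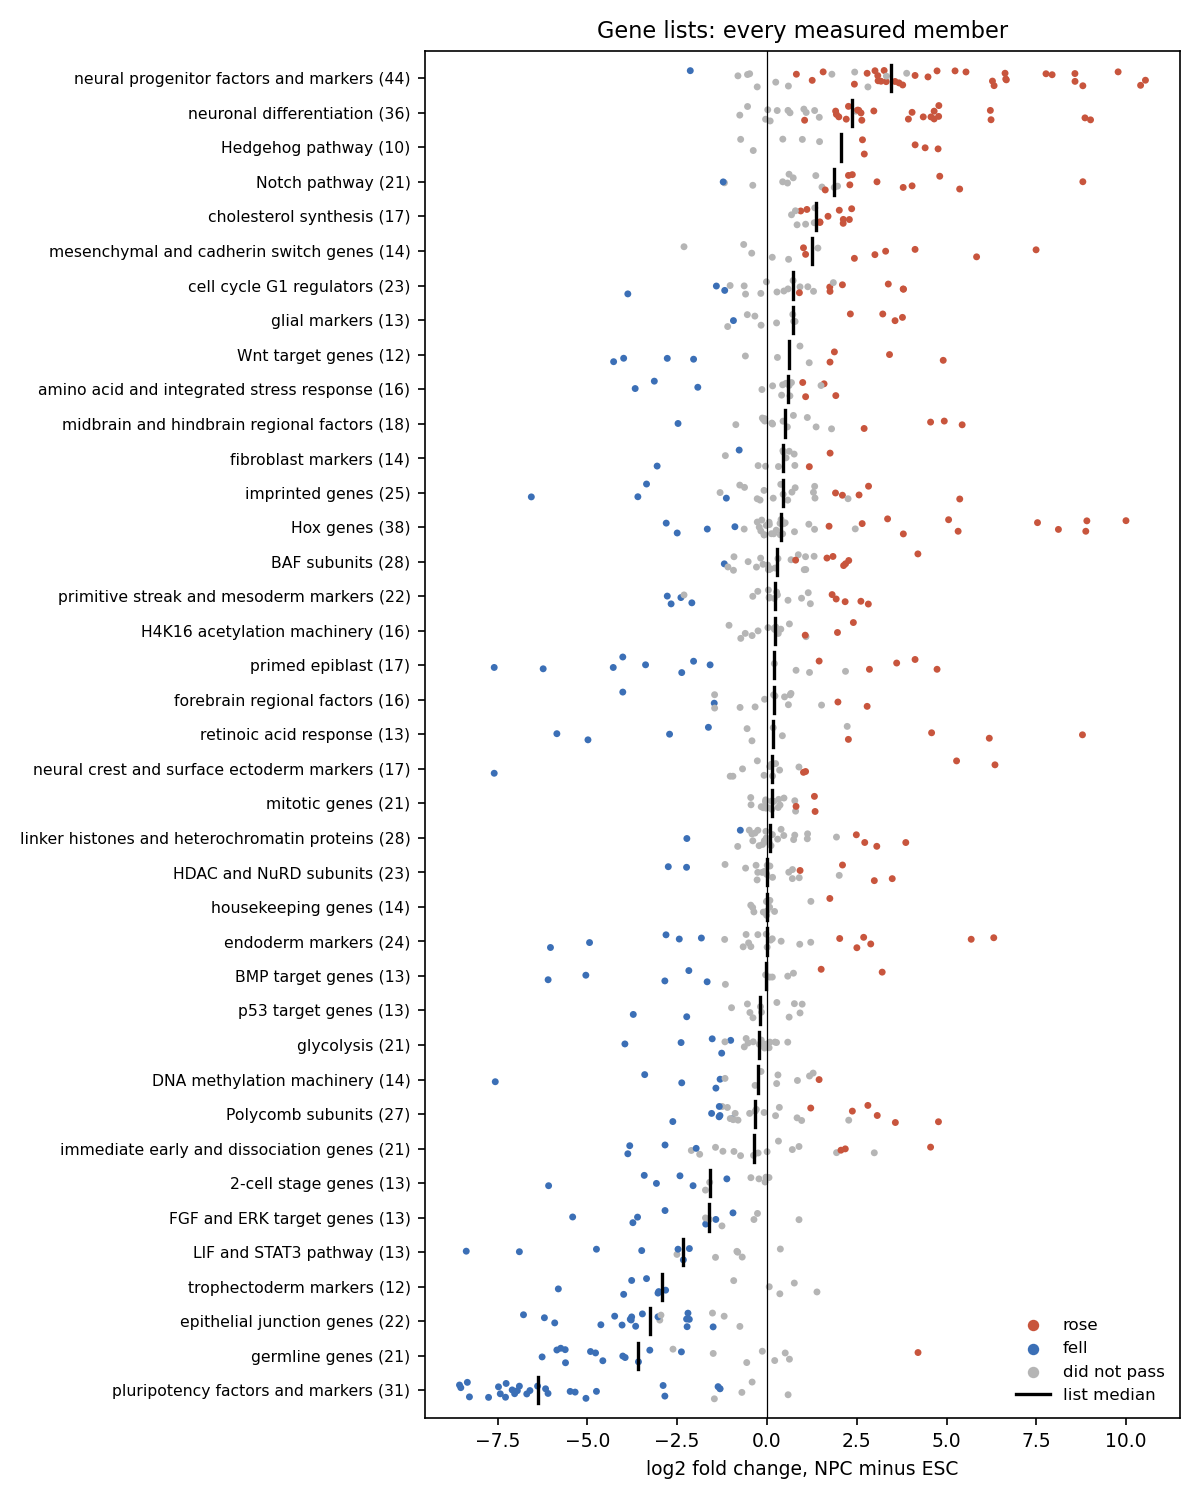
Log2 fold change (NPC minus ESC) of every measured member of the 39 gene lists, with the number of measured members in brackets, red for genes that rose, blue for genes that fell, grey for genes that did not pass, and a black bar for the list median. Medians ran from -6.38 for pluripotency factors to 3.45 for neural progenitor factors.

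Markers of other cell types that the sort could hold were set beside these groups. Of the germline genes, 13 of 21 measured members fell and 1 rose (14 and 1 adjusted over the list alone, 15 and 1 with the block). Hormad1 fell by 6.26 ± 0.20 and Stra8 fell by 5.85 ± 0.49 (-1.65 and -1.83 with values under 6 set to 6). Tdrkh rose by 4.21 ± 0.39 (camera adjusted p = 3.73e-07, and adjusted p = 0.145 with an estimated correlation). Of the 2-cell stage genes, 6 of 13 measured members fell and 0 rose (7 and 0 adjusted over the list alone, 6 and 0 with the block), with Zscan4f at -6.08 ± 0.72; the Zscan4 genes are near-identical copies, so single members are uncertain (camera adjusted p = 0.000578, and adjusted p = 0.169 with an estimated correlation). Of the trophectoderm markers, 7 of 12 measured members fell and 0 rose (7 and 1 adjusted over the list alone, 8 and 1 with the block). Tfap2c fell by 5.81 ± 0.25 and the keratin gene Krt8 fell by 3.77 ± 0.27 (camera adjusted p = 0.00102, and adjusted p = 0.124 with an estimated correlation). Mesoderm markers went both ways, as 5 of 22 measured members rose and 4 fell (5 and 4 adjusted over the list alone, 6 and 5 with the block), with Cdx1 at -2.77 ± 0.25 and Eomes at -2.67 ± 0.34 (camera adjusted p = 0.702). Evx1 rose by 2.82 ± 0.48, a call that ended in 1 of 6 leave-one-out fits (adjusted p = 0.0507 without ESC replicate 1) and with values under 6 set to 6 (adjusted p = 0.262). With the replicate block Evx1 passed (adjusted p = 0.00185). Of the endoderm markers, 6 of 24 measured members rose and 5 fell (7 and 5 adjusted over the list alone, 7 and 6 with the block): Cxcr4 rose by 6.31 ± 0.44 and Foxa2, which is also expressed in the floor plate, by 5.69 ± 0.35, and Spink1 fell by 6.03 ± 0.48 (camera adjusted p = 0.980). Of the neural crest and surface ectoderm markers, 4 of 17 measured members rose and 1 fell (5 and 1 adjusted over the list alone, 5 and 3 with the block), with Tfap2b at 6.35 ± 0.30 (camera adjusted p = 0.437). Of the glial markers, 4 of 13 measured members rose and 1 fell (4 and 3 adjusted over the list alone, 5 and 2 with the block). Slc1a2 and Olig2, which rose by 3.77 ± 0.16 and 3.57 ± 0.53, lost their calls with values under 6 set to 6 (camera adjusted p = 0.247). Glul fell by 0.93 ± 0.23, a call that ended in 5 of 6 leave-one-out fits (highest adjusted p 0.134 without ESC replicate 1) and with values under 6 set to 6. The change of Glul stayed at -0.93 with that floor and passed with the replicate block (adjusted p = 0.0117). Of the fibroblast markers, 2 of 14 measured members rose and 2 fell (3 and 3 adjusted over the list alone, 3 and 3 with the block); Col1a2 rose by 1.76 ± 0.29 (camera adjusted p = 0.514). Thy1 fell by 3.06 ± 0.52, a call that ended in 1 of 6 leave-one-out fits (adjusted p = 0.0507 without NPC replicate 1) and with values under 6 set to 6 (adjusted p = 0.0710).

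Of the metabolic and growth lists, cholesterol synthesis was higher: 10 of 17 measured members rose and 0 fell (13 and 0 adjusted over the list alone, 15 and 0 with the block). Hmgcs1, an early enzyme of the pathway, rose by 2.36 ± 0.38 and Cyp51 by 2.29 ± 0.22 (camera adjusted p = 1.32e-05, and adjusted p = 0.0662 with an estimated correlation). Of the glycolysis genes, 5 of 21 measured members fell and 0 rose (6 and 0 adjusted over the list alone, 7 and 1 with the block); Pdk1, a kinase that restrains pyruvate oxidation, fell by 2.39 ± 0.22 (camera adjusted p = 0.0349). The glycolysis call was lost with an estimated correlation (adjusted p = 0.536), with the replicate block (adjusted p = 0.0624), without ESC replicate 2 (adjusted p = 0.0802) and without NPC replicate 1 (adjusted p = 0.0724). Of the G1 regulators, 7 of 23 measured members rose and 3 fell (8 and 3 adjusted over the list alone, 11 and 3 with the block): Mycl and Cdkn2c rose by 3.80 ± 0.48 and 3.79 ± 0.32, and Myc fell by 3.87 ± 0.49 (camera adjusted p = 0.121). Of the mitotic genes, 3 of 21 measured members rose and 0 fell (0 and 0 adjusted over the list alone, 5 and 0 with the block). The proliferation marker Mki67 rose by 1.32 ± 0.32, a call that ended in 5 of 6 leave-one-out fits and with values under 6 set to 6 (highest leave-one-out adjusted p 0.127 without NPC replicate 1, camera adjusted p of the list = 0.247). The change of Mki67 stayed at 1.32 with that floor and passed with the replicate block (adjusted p = 0.00409). Of the housekeeping genes, 1 of 14 measured members rose and 0 fell (0 and 0 adjusted over the list alone, 2 and 0 with the block), with a median of 0.00. Hprt rose by 1.75 ± 0.43, a call that ended in 4 of 6 leave-one-out fits and with values under 6 set to 6 (highest leave-one-out adjusted p 0.133 without NPC replicate 1, camera adjusted p of the list = 0.807). With the replicate block Hprt passed (adjusted p = 0.00419). The median and the mean of a list differed in sign for 4 lists that did not pass: primed epiblast (0.21 and -0.61), forebrain (0.20 and -0.03), endoderm (-0.01 and 0.13) and Polycomb (-0.33 and 0.23). Their camera directions were downward, upward, downward and downward.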

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

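The test of the unnamed probes was added after the table was seen, whereas the count of splits was planned. Probes without a gene name here showed a signal in data that the comparison of genes did not use. With limma, 1173 of the 25055 unnamed probes (4.68%) passed at an adjusted p under 0.05, 546 higher and 627 lower in NPC, and 1701 passed with the replicate block. The largest rises were of A_30_P01024930, by 10.74, and A_30_P01024432, by 10.72 on the log2 scale, and the largest falls were of A_30_P01020109, at -9.22, and A_30_P01022373, at -8.81. What these probes measure was not analysed here.

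The splits of the 6 arrays into 3 against 3 are 10 in number, too few for a share under 0.05. In 1 of 10 splits, the real one, 2423 genes were called higher, and the highest count in the others was 0; the same held for 2089 genes called lower and 4138 changed at least 2-fold, each with 1 split as large and 0 as the highest other. For lists shifted upward the real split gave 8 and the highest other 6, and for lists shifted downward 8 and 5, again with 1 split as large. Of the splits that part all pairs, the others called 0 genes with the block. Every split but the real one mixes ESC and NPC arrays, so the difference between ESC and NPC enters the spread within its groups. Counts of 0 genes in those splits were thus to be expected and say nothing for the calls.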

How the results depend on the processing

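Alternatives chosen after the data were seen were the floor of 6, leaving out both replicate 3 arrays, normalisation of named probes alone, the block with each replicate number left out, and the block with an estimated correlation. Of the 4512 called genes, 14 had the opposite sign with the mean of all probes and 0 under each of the other settings that were compared gene by gene. With array weights, which stopped before convergence, 6272 genes were higher, 5736 lower and 6982 changed at least 2-fold. ESC replicate 1 got a weight of 98.9 there, against 0.155 to 1.43 for the other arrays. Results with array weights thus rest mostly on 1 ESC array and are no measure of stability. With the replicate block, 4147 were higher and 3660 lower; the block ended the calls of the BAF and glycolysis lists, and ended no call of another list. It added 10 named genes to those past the threshold and ended the call of none, including those that leave-one-out fits ended. The fits that left out 1 array had no block, and each broke a pair. BAF was lost with array weights as well (adjusted p = 0.130), as was Hedgehog (0.0598), and BAF and glycolysis were lost without the dimmest 25% of probes (0.0507 for both). BAF was also lost without the dimmest 50% (0.0590) and without both replicate 3 arrays (0.112), where the G1 regulators passed (0.0434), and Hox was lost with the block and without replicate 1 (0.104). With an adjusted p under 0.01 the counts were 1362, 1203 and 2562, and with values under 6 set to 6 they were 1527, 1297 and 2313. With an estimated correlation 0 lists were shifted upward and 1 downward, and with the block as well 0 and 0. Leaving out 1 array gave 1475 to 2644 genes higher, 1289 to 1923 lower and 2764 to 4334 changed at least 2-fold, with 7 to 9 lists upward and 7 to 8 downward; leaving out a replicate number with the block gave 2411 to 2997, 1974 to 2432 and 4385 to 5202. Of all 4512 calls, leaving out 1 array kept 60.9% (without ESC replicate 1) to 87.3% (without NPC replicate 3). With values under 6 set to 6, 58.2% were kept, and 88.4% with the mean of all probes. Many named genes were chosen for large changes, so their losses do not stand for all calls. Of 175 named genes past the threshold, 29 lost the call in at least 1 leave-one-out fit, 26 with values under 6 set to 6 and 10 with the mean of all probes. Among these 26, Msl1, Mki67, Uhrf2, Glul, Rbpj and Id4 kept the same log2 change, so dim signals of their own did not end their calls. With the mean of all probes the sign of Zic1 (1.85) and Msi1 (1.75) was reversed, and with array weights that of Ogt (-0.98); the cause was not tested. The scalings to median, 75th percentile and quantiles left every value as it was, because the arrays already share 1 distribution, and say nothing about stability. The alternative pseudocount was not run, since the values are logarithms. How far signals near background limit the fold changes is unknown without detection calls.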

Other observations

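The tests of the Hox genes and of the signal left in NPC were chosen only after the result was seen. Further lists held members that moved both ways. Of the retinoic acid response genes, 4 of 13 measured members rose and 4 fell (5 and 4 adjusted over the list alone, 5 and 4 with the block): Cyp26b1, which degrades retinoic acid, rose by 8.78 ± 0.28 and the binding protein gene Crabp1 by 6.19 ± 0.38, while Stra8 fell by 5.85 ± 0.49 (-1.83 with values under 6 set to 6; camera adjusted p = 0.811). Of the Wnt target genes, 4 of 12 measured members rose and 4 fell (4 and 4 adjusted over the list alone, 5 and 4 with the block), with Lgr5 at 4.91 ± 0.33 and Sp5 at -4.27 ± 0.45 (camera adjusted p = 0.930). Of the BMP targets, 5 of 13 measured members fell and 2 rose (5 and 2 adjusted over the list alone, 6 and 2 with the block); Bmp4 itself fell by 6.09 ± 0.27 and Dusp9 fell by 5.04 ± 0.36 (camera adjusted p = 0.133). Id4 rose by 3.21 ± 0.62, a call that ended in 2 of 6 leave-one-out fits (highest adjusted p 0.0680 without ESC replicate 1) and with values under 6 set to 6. The change of Id4 stayed at 3.21 with that floor and passed with the replicate block (adjusted p = 0.0064). Of the imprinted genes, 5 of 25 measured members rose and 4 fell (8 and 5 adjusted over the list alone, 9 and 6 with the block): Peg12 rose by 5.37 ± 0.30, and Phlda2 fell by 6.56 ± 0.30 (camera adjusted p = 0.465).

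Of the amino acid and stress response genes, 4 of 16 measured members rose and 3 fell (4 and 3 adjusted over the list alone, 4 and 3 with the block), with Cth at -3.67 ± 0.53 and Slc7a3 at -3.14 ± 0.35, while Aldh18a1, chosen after its values were seen, rose by 1.92 ± 0.21 (median of the list 0.57, camera adjusted p = 0.322). Of the immediate early and dissociation genes, 3 of 21 measured members rose and 4 fell (5 and 6 adjusted over the list alone, 5 and 8 with the block), with Egr2 at 4.55 ± 0.31 and Myc at -3.87 ± 0.49 (camera adjusted p = 0.541). Of the p53 targets, 2 of 13 measured members fell and 0 rose (2 and 0 adjusted over the list alone, 3 and 3 with the block); Perp fell by 3.72 ± 0.18 and Pmaip1 fell by 2.23 ± 0.39 (camera adjusted p = 0.464).

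Arrays with the same replicate number deviated together in both groups. The difference between replicates 3 and 2 correlated between ESC and NPC with r = 0.792 across 21893 genes, which are not independent, and 1030 genes were at least 2 higher and 221 at least 2 lower on the log2 scale in replicate 3 of both groups. If this came from technical effects of single probes, probes of the same gene would share it poorly: across 3572 genes, the correlation between probes was 0.214 for this difference and 0.709 for NPC minus ESC, a ratio of 0.301 (95% bootstrap interval 0.250 to 0.355), although at the brighter probe it correlated between groups with r = 0.903. That is consistent with probe-specific technical differences between the sets of arrays. Replicate sets at different points between ESC and NPC stay open at r = -0.250 with NPC minus ESC of replicate 1. The median difference was -0.19 for pluripotency and -0.23 for neural progenitor genes against -0.17 for all genes, whose SD was 1.16. Other lists lay further off: 0.70 for immediate early and dissociation genes, -0.93 for p53 targets, -0.89 for Polycomb and -0.81 for the H4K16 machinery. The H4K16 list had a median of 0.23 between NPC and ESC. Why these lists differed between replicates was not tested. The spread of the list members is not given here, so these medians do not decide the question. No other biological explanation was tested.

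Hox genes split by cluster position. The paralog group correlated with the log2 fold change across 38 Hox genes, which are not independent (Spearman's rho = -0.553, Pearson's r = -0.623), but this was measured on the values in which the split was noticed and so describes them without testing it. Posterior probes too dim to show a rise stay open, and the 4 falls in groups 9 to 13 were of genes under 6 in both groups. Of groups 9 to 13, 1 gene reached a mean of 8 in either group. It was Hoxa9, named after its values were seen, which read 10.30 in ESC and 10.13 in NPC, so its probe was not dim. Whether that probe reads Hoxa9 alone was not checked. A gene that does not rise from a low signal cannot reach 8, so the count decides nothing about the others.

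The signal of pluripotency genes was left in the sorted NPC to unequal degrees. Among the 26 members that fell, 12 read under 6 in NPC, so values under 6 were set to 6 and the percentages of these members are upper bounds. The signal left in NPC then ran from 0.367% (Zfp42) to 40.5% (Tet2) of that in ESC, and was 0.465% for Pou5f1, which read 6.67. Without detection calls, signals as low as that of Pou5f1 in NPC cannot be told from background. A single share of unconverted ES cells would leave about the same percentage of each member, but the highest was at least about 110 times the lowest. The range of 68.2 to 178 at 2 SE on each side is too narrow, since these are extremes of 26 members and the lowest rests on the floor. Tet2, Jam2 (38.9%), Tbx3 (13.9%) and Mybl2 (13.5%) stood far above the median of 1.33%. Probes of 1 gene also differed: Gdf3 gave -7.02 and -2.09, and Jam2 gave -2.73, -1.36 and -0.45. The range between members can thus come in part from the probes and does not decide the question by itself. All probes of Tet2 (-1.64, -1.30 and -0.87) and Mybl2 (-2.89 and -2.23) fell little. For these genes the values argue against such a share as the whole cause, provided that the probes read them alone, which was not checked. The spread among the rest was not tested. A small share of ES cells beside transcripts made by the NPC themselves stays open.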
